A study of Homo sapiens with 2 samples.

How the data were processed

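Gene expression was measured in 2 RNA samples of the esophageal squamous carcinoma line KYSE-140, 1 of CD90+ and 1 of CD90- cells, each on 1 Affymetrix U133 Plus 2.0 array, a one-colour array read as biotin label. Groups were taken from the cell population label. Per the submitters' processing notes the authors used MAS5, the Affymetrix algorithm that combines the perfect-match and mismatch probes of a probe set into 1 signal; its version and settings are not given in the sources used here. The deposited table holds linear signal intensities, 54675 probe sets by 2 arrays, all above 0 and up to 44705, and the 2 to 98% trimmed mean was 499.9 on both, so the authors had scaled each array to a common mean of about 500. MAS5 subtracts mismatch signal, which makes ratios of dim probe sets noisy and leaves very small values. The scanner files and detection calls were not used here. No value column was left unused.

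Probe sets were named through the platform annotation, with gene identifiers checked against the RefSeq gene table of GRCh38.p14. Of the probe sets 41097 had 1 gene symbol, 1801 had several and were not named, and 11777 were unnamed here, 11721 of them other than control probe sets. The 62 control probe sets were left out of all gene counts. The identifier of 41043 matched the reference, and 54 kept the annotation's symbol. Symbols covered 19775 genes. Some genes of the fixed lists had no probe set with a single symbol and were not analysed here. The reference assembly was used for symbols, for the chromosome and order of genes, for distances between genes and for annotated gene span. No coordinates are given here because no genome build goes with the array values.

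The floor, 71.6, was the geometric mean of both arrays' medians over all probe sets other than controls, that is the 50th percentile; 50.1% of probe sets reached it in CD90+ and 49.9% in CD90- cells. Signals under it were set to it, and the log2 ratio, CD90+ over CD90-, was taken. One probe set stood for each gene, the one with the highest mean log2 signal, with the _x_at class, which is prone to cross-hybridisation, used only where a gene had no other. A gene was measured if that probe set reached the floor on at least 1 array. Genes were counted at a 2-fold difference. With 1 array per population nothing estimates the spread between samples, so there is no test, p-value or interval. Agreement of probe sets was described by the pooled SD of log2 ratios within genes, which was 0.40 where the brightest probe set was under 4 times the floor, 0.33 from 4 to 16 times and 0.28 from 16 times.

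The main design, the floor, 33 gene lists and the rule for named genes were fixed before the data were examined. The rule named THY1; the 12 genes with the highest and the 12 with the lowest ratio among genes with a brighter side of at least 4 times the floor, a symbol other than a LOC number and all measured probe sets of one sign; and in each list up to 4 members each way beyond 2-fold, or the 2 brightest where none was. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size drawn in 20 bins of mean signal. That percentile describes these arrays and is not a test, since genes are not replicates. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.

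For the order of genes, medians were taken over 50 consecutive genes on a chromosome, using genes at or above the floor on both arrays, and compared with 1000 shuffles. The local median of a gene is that of its 50 nearest neighbours by start position, itself left out. To measure a run or a step in genes that did not choose it, the search was made in every other gene and the value taken in the genes left out. This part was added after the data were seen.

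The procedure was tested on simulated data made from the mean signals of the probe sets of this comparison, run on 12401 genes. Of the genes changed by 2-fold 54% were counted in the right direction, of those changed 3-fold 98%, and of those changed 4-fold or 8-fold 100%. Of 12099 unchanged genes 15 were counted. The changes were planted only in genes with a mean signal above 4 times the floor, so recovery nearer the floor was not measured. The noise was assumed, of one size for probe sets at or above the floor and wider below it. The shares recovered and the 15 unchanged genes counted follow largely from that choice, and a 2-fold change lies at the threshold itself. At or above the floor the assumed noise was smaller than the pooled SD of 0.40 seen where the brightest probe set was under 4 times the floor. It held no spread between sorts.

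The alternatives planned beforehand were no floor; floors at the 25th and 75th percentiles; quantile normalization; scaling to a median ratio of 0; loess of the ratio on signal with a span of 0.3; the mean over a gene's probe sets; leaving out the _x_at, _s_at and _a_at classes; the probe set with the smallest change; a filter on mean signal; the floor as an offset; and thresholds of 1.5-fold and 4-fold. Subtraction of the local median was added later. Leaving out replicates or comparing other splits of the samples was not possible with 1 sample per population.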

Results

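KYSE-140, an established line of human esophageal squamous cell carcinoma, was parted by flow cytometry into cells that carried the surface glycoprotein CD90 and cells that did not, and total RNA of each fraction was hybridised to 1 Affymetrix U133 Plus 2.0 array. CD90, encoded by THY1, is a cell surface protein of fibroblasts, endothelial cells, neurons and some tumour cells. The published study of these cells asked whether the CD90+ fraction holds tumour-initiating cells, and the arrays ask which transcripts set it apart. The data comprised 2 samples, 1 CD90+ and 1 CD90-, and 54675 probe sets. No sort was repeated, so no difference below carries a replicate error, no test between the populations was possible, and every fold describes these 2 RNA samples. Both arrays had the same 2 to 98% trimmed mean of 500 (499.9 on each), and their medians were 72.2 for CD90+ and 71.3 for CD90- cells. Signals below a common floor of 71.6 were set to it, so a fold with one side under the floor is written as a lower bound, and 12466 genes reached the floor on at least 1 array. The number of arrays limits the precision. The closest thing to a repeated measurement was the agreement of different probe sets of a gene, whose log2 ratios had a pooled SD of 0.31 over 5709 genes; this covers array noise and not the spread between sorts.

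THY1 itself was higher in the CD90+ fraction on all of its 3 probe sets, in the direction of the sort. Of the probe sets that match several transcripts of the gene, the brighter read 293 in CD90+ and 78.9 in CD90- cells, a 3.72-fold difference and a log2 ratio of 1.90. The second read 244 against 49.6, at least 3.41-fold. The third, of a class prone to cross-hybridisation, read 517 against 35.5, at least 7.21-fold. In CD90- cells the transcript was thus close to the floor on 1 probe set and under it on the others. With the floor at the 75th percentile THY1 was not measured. The median log2 ratio of the 50 genes nearest to THY1 by start position was 0.25.

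Both fractions were alike for most genes, with an expression difference of at least 2-fold at 526 of the 12466 measured genes. In CD90+ cells 308 genes were at least 2-fold higher and 218 at least 2-fold lower, while 85.9% of the measured genes differed by less than 1.5-fold. Across the 25509 probe sets at or above the floor on both arrays, the log2 signals correlated with r = 0.98, a value across probe sets, which are not replicates. Of the 308 higher genes 68, and of the 218 lower genes 41, had one side under the floor. Where a gene counted as higher had other measured probe sets, the mean of their log2 ratios was taken. That mean was also at least 1.5-fold higher in 67 of 111 cases (60.4%), against 5.96% over all genes with a second probe set. For the lower genes this held in 45 of 87 cases (51.7%), against 6.29%. The counts depend on the floor: with the floor at the 75th percentile of signals 89 genes were higher and 66 lower, and with it at the 25th percentile 1122 were higher and 835 lower.

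**Figure D1:**
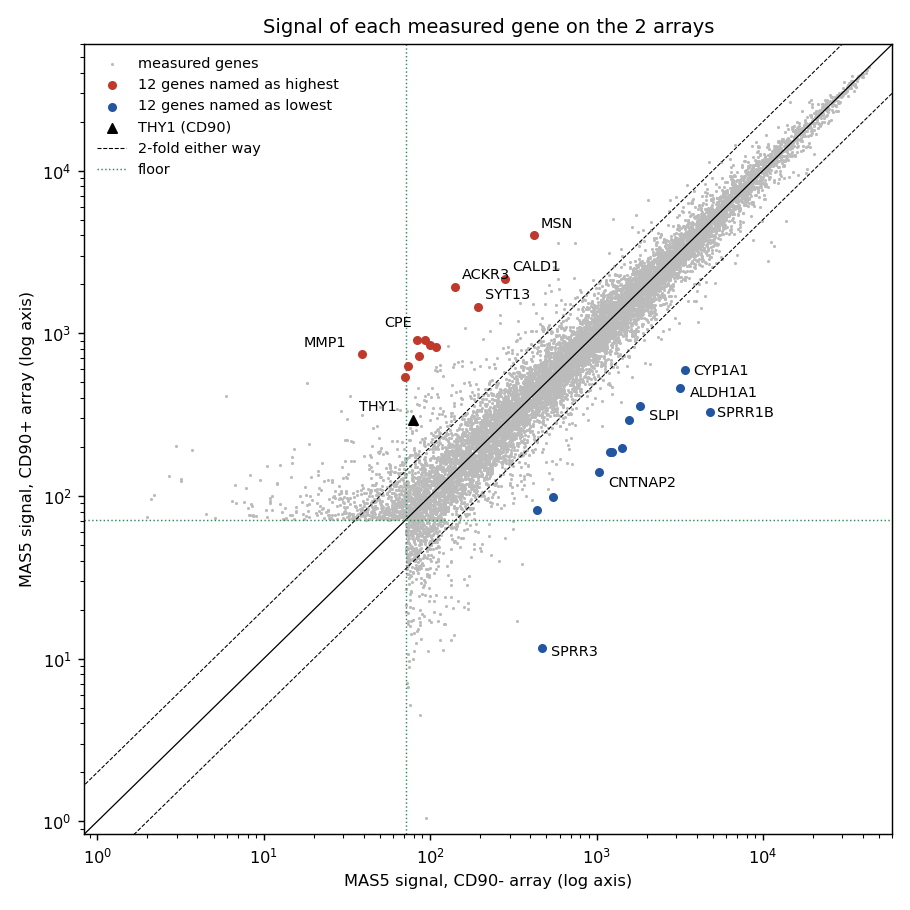
MAS5 signal of each of the 12466 measured genes on the CD90- array (horizontal, log axis) and the CD90+ array (vertical, log axis), with the 12 genes named as highest in red, the 12 named as lowest in blue and THY1 as a black triangle; the dashed lines mark 2-fold and the dotted lines the floor of 71.6. Most genes lie between the dashed lines, ACKR3 at 1935 against 141 stands far above them and SPRR1B at 329 against 4818 far below.

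The 12 genes named for the highest ratios in CD90+ cells ranged from 13.7-fold to 7.50-fold. ACKR3, an atypical receptor for the chemokine CXCL12, was 13.7-fold higher (1935 against 141). CPE, a carboxypeptidase that processes prohormones, was 11.0-fold higher (913 against 83.2), and MMP1, the interstitial collagenase, at least 10.4-fold (746 against 38.8). KMO, an enzyme of tryptophan degradation, was 9.70-fold higher (910 against 93.8). MSN, or moesin, which links actin to the membrane, was 9.58-fold higher (4025 against 420), and CALD1, or caldesmon, an actin-binding protein, 7.70-fold (2166 against 281) with all of its 4 measured probe sets going the same way. ETS1 was 8.54-fold higher (631 against 73.9), the cytokine IL18 8.50-fold (729 against 85.8), and FSTL1, a secreted glycoprotein, 8.48-fold (845 against 99.7). EHF, an epithelial ETS factor, was at least 7.56-fold higher (541 against 71.1), TRIM54 7.55-fold (819 against 108) and SYT13, a synaptotagmin, 7.50-fold (1457 against 194). With the floor at the 75th percentile the bounds of MMP1, ETS1, IL18 and EHF were under 2-fold, and by their least changed probe set ACKR3, CALD1, EHF and SYT13 were under 2-fold.

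The genes with the lowest ratios in CD90+ cells included proteins of the cornified envelope, an aldehyde dehydrogenase and a neuronal adhesion molecule. SPRR1B, a cornified envelope precursor, was 14.6-fold lower (329 against 4818), and its relative SPRR3 at least 6.56-fold lower (11.6 against 470). CNTNAP2, a neuronal adhesion molecule, was 7.39-fold lower (140 against 1034) on 4 concordant probe sets. GPR183, an oxysterol receptor, was 7.12-fold lower (199 against 1413). ALDH1A1, a retinaldehyde dehydrogenase often used as a stem cell marker, was 6.91-fold lower (462 against 3194). The RNA-binding protein KHDRBS3 was 6.60-fold lower (188 against 1239), the ephrin receptor EPHA7 6.42-fold (187 against 1201), and CYP1A1, the best known target of the aryl hydrocarbon receptor, 5.65-fold (599 against 3385). The phosphatase PPM1L was 5.50-fold lower (98.9 against 544), the potassium channel KCNMA1 5.39-fold (292 against 1575), the sodium-calcium exchanger SLC8A1 5.32-fold (82.6 against 439) and the protease inhibitor SLPI 5.12-fold (357 against 1830). SPRR3, PPM1L and SLC8A1 were under 2-fold with the floor at the 75th percentile, and EPHA7 and KCNMA1 by their least changed probe set. Without the _x_at, _s_at and _a_at classes 18 of the 24 genes named for their ratios had a value, and KCNMA1 was under 2-fold.

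Mesenchymal genes were higher in CD90+ cells as a group. Of 24 measured members of the mesenchymal list 10 were at least 2-fold higher, 1 was at least 2-fold lower and 13 lay between. The list's median log2 ratio of 0.64 stood at percentile 100 of 10000 random lists matched on signal, the central 95% of which ran from -0.16 to 0.17. After MSN, FSTL1 and CALD1 the largest difference was in AXL, a receptor tyrosine kinase, which was 4.50-fold higher (461 against 102). Among members singled out after their values were seen, the intermediate filament VIM was 2.38-fold higher (6588 against 2771), the fibrillar collagen COL5A1 4.48-fold (1029 against 230), the matrix protein TNC 2.33-fold (8127 against 3494) and the EMT transcription factor TWIST1 2.06-fold (634 against 307). NT5E, which encodes the surface nucleotidase CD73, was the member at least 2-fold lower, by at least 2.60-fold (61.3 against 186). FN1, SNAI1, ZEB1, ZEB2, CDH11, PRRX1, TPM2, MYL9 and GREM1 stayed under the floor on both arrays. The epithelial junction list showed no such shift: 27 of its 29 measured members lay between, its median was -0.06 at percentile 11.8, the desmosomal PKP2 was 2.30-fold higher and the epithelial factor GRHL1 2.42-fold lower. GRHL1 sits among neighbouring genes whose median log2 ratio was -0.49. PKP2, at a log2 ratio of 1.20, sits among neighbours with a median of 0.23. E-cadherin (CDH1), also singled out afterwards, read 13150 against 11992 and N-cadherin (CDH2) 2340 against 2404.

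Matrix proteases and ETS factors contained some of the largest differences. In the protease and inhibitor list 7 of 25 measured members were at least 2-fold higher and 0 at least 2-fold lower. Besides MMP1, the gelatinase MMP2 was 5.70-fold higher (618 against 108), the stromelysin MMP10 4.40-fold (1164 against 265) and PLAU, the urokinase plasminogen activator, 3.19-fold (632 against 198). The list's median was 0.20 at percentile 98.9, with a mean of 0.58, but the median stood at percentile 47.6 with the lower floor, 67.7 without probe sets shared between transcripts and 64.6 by the least changed probe set. The ETS family was followed up in the published study of these cells, so its list is not independent evidence of direction. Of its 18 measured members 3 were at least 2-fold higher, ETS1, EHF and ETS2 (2.38-fold, 1037 against 435), 0 were lower by that much and 15 lay between. The family median of 0.08 lay at percentile 83.0 and turned to -0.06 when the median of the neighbouring genes was subtracted.

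**Figure D2:**
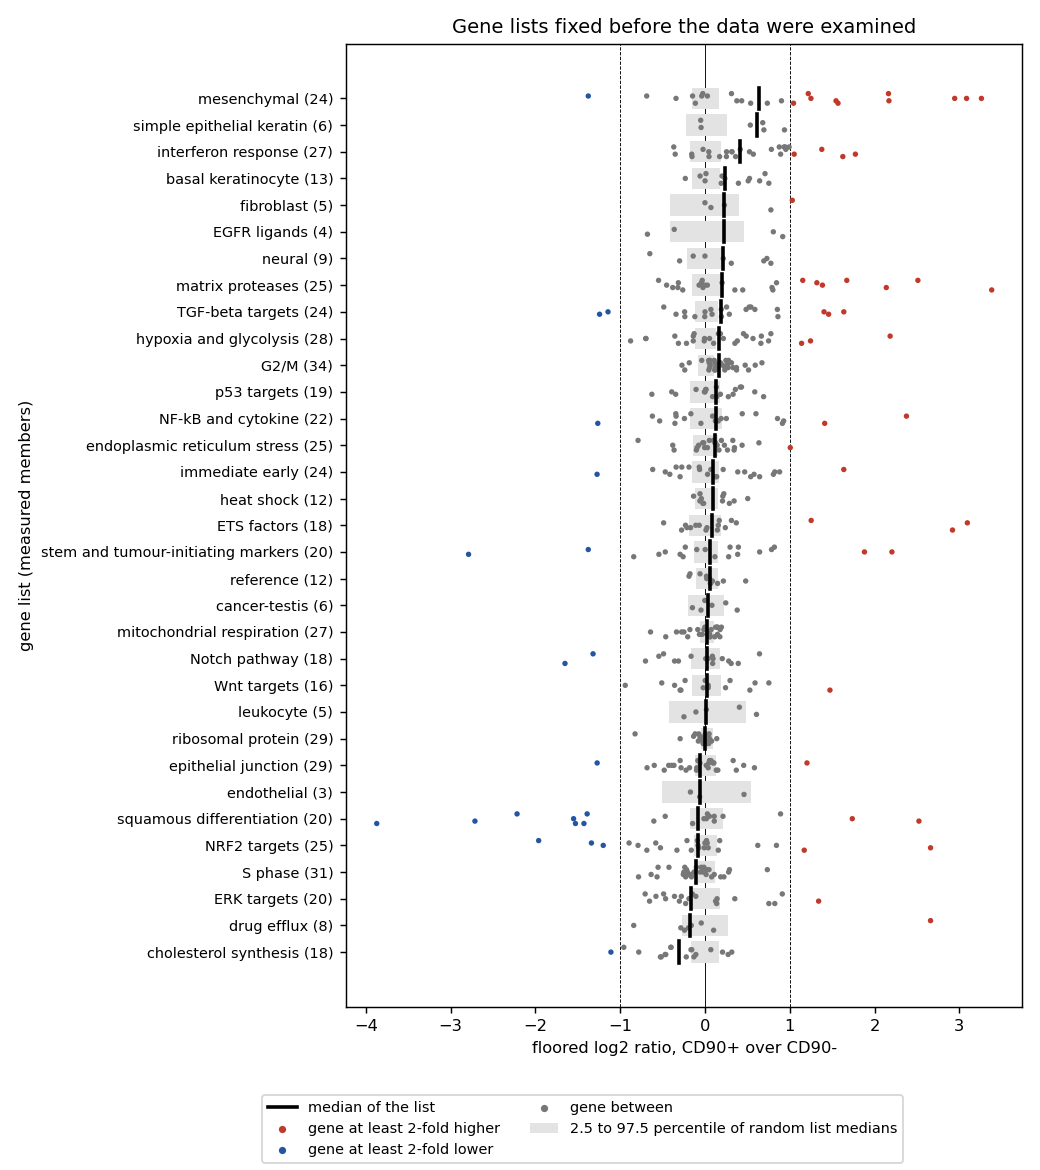
Floored log2 ratio, CD90+ over CD90-, of each measured member of the 33 gene lists (points; red at least 2-fold higher, blue at least 2-fold lower, grey between), with the list's median as a black bar and the central 95% of medians of random lists as a grey band. The medians of the mesenchymal list (0.64) and the interferon list (0.42) lie right of their bands and that of the cholesterol list (-0.31) left of its band.

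Squamous differentiation genes gave the most members at least 2-fold lower of any list, although its median lay inside the central 95% of random lists in the main setting. Of 20 measured members 7 were at least 2-fold lower, 2 higher and 11 between, and the median was -0.08 at percentile 16.5. After subtraction of the neighbours' median the list stood apart, at -0.20 and percentile 1.24. Besides SPRR1B and SPRR3, SPRR1A was at least 4.65-fold lower (17.0 against 333) and the airway and esophageal protease TMPRSS11D 2.93-fold lower (421 against 1233). The SPRR genes are close relatives that lie side by side, so their probe sets are not independent. The members that went the other way were FLG, or filaggrin, at least 5.75-fold higher (412 against 32.8), and the kallikrein KLK5, 3.33-fold higher (275 against 82.4). Another 20 members with a probe set, among them involucrin (IVL) and KRT4, stayed under the floor on both arrays in the probe set that stood for them. Basal keratinocyte genes had 0 of 13 members beyond 2-fold, with KRT5 at 19357 against 19208 and SOX2 at 23329 against 27407, and yet 11 of the 13 ratios were above 0 and the median of 0.23 stood at percentile 99.6. The 6 measured genes of the simple epithelial list had a median of 0.61 at percentile 100, with KRT19 at 8526 against 5888 and KRT18 at 14729 against 15209, none beyond 2-fold, and percentile 96.3 by the least changed probe set.

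Stem and tumour-initiating markers went both ways. Of 20 measured markers 2 were at least 2-fold higher, 2 lower and 16 between, with a median of 0.06 at percentile 75.5. That median left the central 95% in opposite directions, at -0.13 and percentile 1.82 with the floor at the 75th percentile and at 0.27 and percentile 99.1 without shared probe sets. ALDH1A3, an aldehyde dehydrogenase related to ALDH1A1, was 4.61-fold higher (335 against 72.6) where ALDH1A1 was lower. The kinase DCLK1 was 3.68-fold higher (2162 against 587), and NT5E was the other marker at least 2-fold lower. The drug transporter ABCC3 was 6.32-fold higher (454 against 71.9), the 1 member of the drug efflux list beyond 2-fold among 8 measured, with a list median of -0.18 at percentile 9.67. ABCC3 and ALDH1A3 read just above the floor in CD90- cells, so both folds depend on it. With the floor at the 75th percentile, 397 on each array, ALDH1A3 is not measured and ABCC3 exceeds the floor only in CD90+ cells.

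Interferon-stimulated genes were higher in CD90+ cells. Of 27 measured members 4 were at least 2-fold higher and 0 lower, 22 had ratios above 0, and the median of 0.42 stood at percentile 100. LGALS3BP was 3.42-fold higher (1810 against 530), IFIT3 3.08-fold (1338 against 434), SAMD9 2.60-fold (766 against 295) and UBE2L6 2.07-fold (684 against 330). SAMD9 and UBE2L6 read under the 75th percentile of signals (397) in CD90- cells, so both folds become smaller bounds with the floor there. UBE2L6 lay among neighbours with a median of 0.16. In the cytokine and NF-kB list, 2 of 22 measured members were higher, the interferon-inducible chemokine CXCL10 by 5.19-fold (599 against 115) and CCL5 by 2.66-fold (372 against 140), and NFKBIZ was 2.40-fold lower (492 against 1181). Its median was 0.13 at percentile 86.5, but stood at percentile 98.8 with the lower floor and after subtraction of the neighbours' median, and turned to -0.17 with the floor at the 75th percentile and -0.048 with the filter on mean signal.

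Genes of TGF-beta signalling and of hypoxia contained further differences. CCN2, a matricellular TGF-beta target, was 3.11-fold higher (416 against 134), the TGF-beta inhibitor PMEPA1 2.75-fold (4504 against 1640) and the receptor TGFBR2 2.65-fold (3137 against 1186). The helix-loop-helix inhibitors ID2 and ID3 were 2.37-fold and 2.21-fold lower, ID2 among neighbours with a median of -0.49. The TGF-beta list had 3 higher and 2 lower of 24, with a median of 0.19 at percentile 99.3 that lay at percentile 89.9 by the least changed probe set and 96.7 with the floor at the 75th percentile. In the hypoxia and glycolysis list 3 of 28 were higher: PGM1, a phosphoglucomutase, 4.54-fold (666 against 147), NDRG1 2.37-fold (1349 against 569) and the glucose transporter SLC2A3 2.20-fold (1782 against 809), the last among neighbours with a median of 0.36. That list's median of 0.17 stood at percentile 99.5, and at percentile 66.2 without shared probe sets and 95.4 by the least changed probe set. Notch target genes HEY1 (log2 ratio -1.32, 2701 against 6748) and HEY2 (at least 3.14-fold, 57.1 against 225) were lower, the 2 members beyond 2-fold among 18 in the Notch list, whose median was 0.02 at percentile 58.2 and turned to -0.20 at percentile 1.89 with the lower floor and to -0.067 by the mean of probe sets.

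Sterol synthesis genes were lower in CD90+ cells by a small amount. Of 18 measured members 1 was at least 2-fold lower and 17 lay between. The 1 was the SREBP regulator INSIG1 (2.16-fold, 617 against 1332, log2 ratio -1.11), among neighbours with a median of -0.19. Ratios above 0 were seen in 4 members, and the list's median of -0.31 stood at percentile 0. In the NRF2 list AKR1C3, an aldo-keto reductase, was 3.90-fold lower (2766 against 10777), AKR1C1 2.53-fold lower (153 against 388) and the heme oxygenase HMOX1 2.30-fold lower (107 against 245), against ABCC3 and ALDH3A1 (2.25-fold) higher; 20 of 25 lay between and the median was -0.08 at percentile 8.94. AKR1C genes are near-identical copies whose probe sets can share signal.

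Cell cycle genes differed little. None of 34 mitotic and 31 replication genes was beyond 2-fold. The mitotic list had 30 ratios above 0 and a median of 0.17 at percentile 99.9, with PTTG1 at 18071 against 14908. The replication list had 10 above 0 and a median of -0.10 at percentile 1.09, with PCNA at 14201 against 16321. ERK target genes had 1 of 20 beyond 2-fold, EPHA2 (2.53-fold higher, 1030 against 407), and a median of -0.17 at percentile 2.03 beside a mean of 0.0036. After subtraction of the neighbours' median the replication list stood at percentile 3.33 and the ERK list at 3.52.

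Markers of other cell types and of handling had few members beyond 2-fold. Of the fibroblast list 5 of 16 genes were measured, with a median of 0.23 at percentile 87.9, or 99.4 without a floor, and 1 member beyond 2-fold, PDPN (2.04-fold higher, 2609 against 1278). COL1A1, singled out after its values were seen, read 2125 against 1240 on its brightest probe set, while COL1A2, COL3A1, DCN and LUM stayed under the floor on both arrays. Leukocyte (5 measured, median 0.02), endothelial (3 measured, -0.06) and neural genes (9 measured, 0.22) had 0 members beyond 2-fold. The neural median lay at percentile 97.45, just inside the central 95%, and outside it in 4 alternatives, at up to percentile 98.6 by the least changed probe set. Immediate early genes, which can respond to handling, had a median of 0.10 at percentile 86.9, with CCN2 higher and NR4A2 at least 2.42-fold lower (66.1 against 173) among neighbours with a median of -0.40. Of 25 endoplasmic reticulum stress genes DDIT4 was 2.01-fold higher (2101 against 1047) and 24 lay between (median 0.12), and of 16 Wnt targets APCDD1 was 2.78-fold higher (481 against 173) and 15 lay between (median 0.02). Heat shock (median 0.09 at percentile 87.7, and at 99.4 with the lower floor and 99.5 after subtraction of the neighbours' median), p53 (0.13 at percentile 93.3, and 97.7 by the least changed probe set), EGFR ligand (0.22 at percentile 84.1, and 98.4 with the lower floor), cancer-testis (0.04), respiratory chain (0.03), ribosomal protein (0.0011) and reference genes (0.06) had 0 members beyond 2-fold. In all, 11 of the 33 list medians lay outside the central 95% of random lists. Lists of independently drawn genes would give 1.65, but these lists share members and neighbouring genes shifted together. That number is therefore no test.

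Signs of RNA quality were similar but not equal on the 2 arrays. The 3' over 5' signal ratio of the ACTB control probe sets was 13.0 for CD90+ and 15.7 for CD90- cells. Their 3' over middle ratio was 3.84 and 4.08. The 3' over 5' ratio of GAPDH was 1.04 and 0.97. On both arrays ACTB signal was thus far higher at the 3' end, a bias that GAPDH did not show. The 18 hybridisation control probe sets had a median log2 ratio of 0.06, and the 24 poly-A control probe sets one of -0.12. Without a floor the poly-A ratios ran from -1.07 to 0.17, and 21 of the 24 reached the floor on both arrays.

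Ratios also followed the order of genes along the chromosomes. Among 11353 genes at or above the floor on both arrays, the median over 50 neighbouring genes ranged from -0.62, from PIAS2 to TIMM21 on chromosome 18, to 0.39, from TIGAR to KLRG1 on chromosome 12. In 1000 shuffles of the genes over the same positions no such median fell below -0.27 or exceeded 0.33. The median over the 767 genes of chromosome 2 was -0.28. Windows of 50 genes with a median beyond every shuffle joined into 12 runs holding 1266 genes, 9 of them lower and 3 higher in CD90+ cells. The best split of chromosome 18, chosen for its step, had a difference of medians of -0.59, against at most 0.53 in size when the genes of that chromosome were shuffled.

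**Figure D3:**
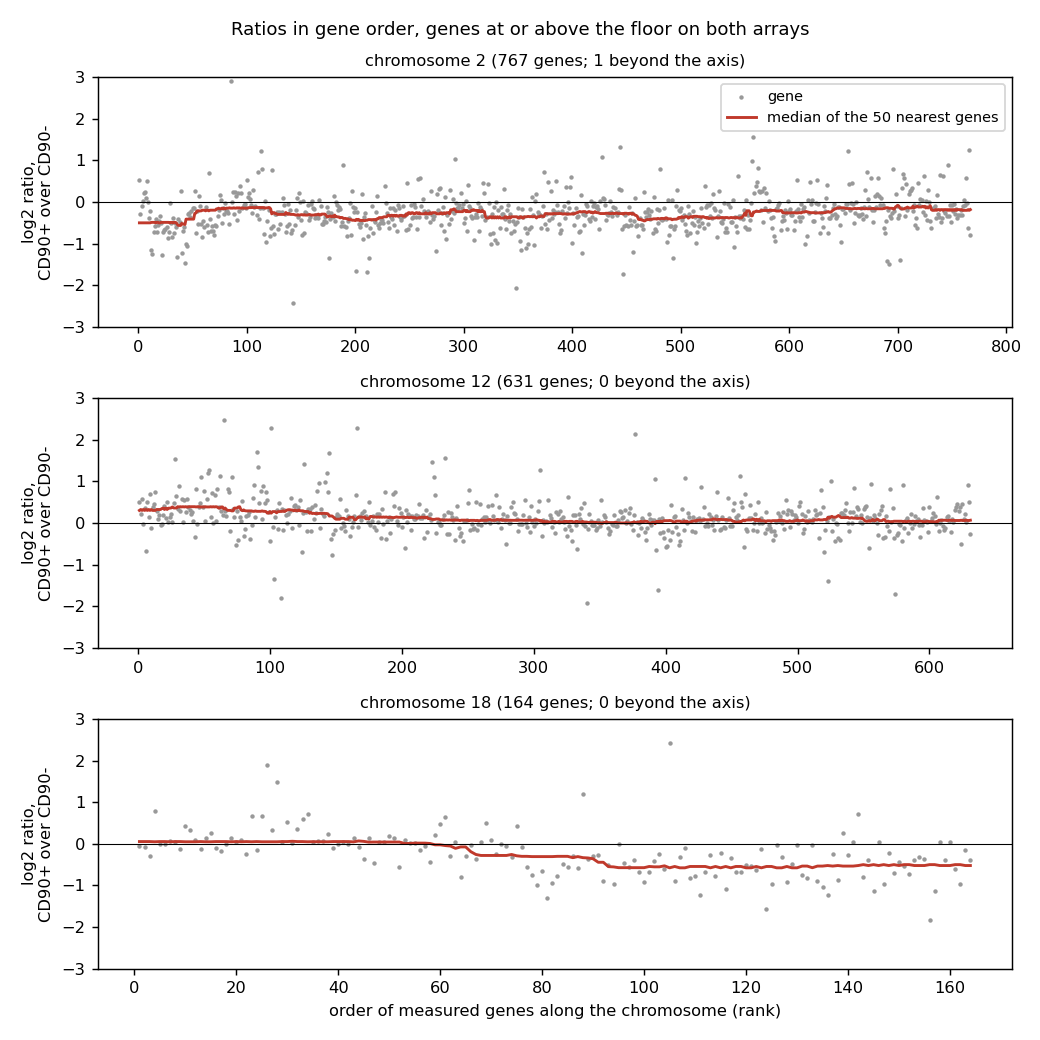
Log2 ratio, CD90+ over CD90-, of genes at or above the floor on both arrays in their order along chromosomes 2, 12 and 18 (points), with the median of the 50 nearest genes as a red line. The line lies below 0 along chromosome 2, above 0 at the start of chromosome 12, and drops along chromosome 18, where the 76 genes before the best split have a median of 0.04 and the 88 after it one of -0.54.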

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

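Probe sets with several gene symbols or none were not part of any comparison, and some of them differed between the fractions. Of 2307 such probe sets with a signal of at least 4 times the floor on either array, 41 were at least 2-fold higher on the CD90+ array and 38 at least 2-fold lower. No spread between samples is known for them.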

How the results depend on the processing

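Subtraction of the local median was chosen after seeing the data, and the other alternatives before. No gene beyond 2-fold among the 94 named genes and none of the 11 lists outside the central 95% of random lists changed sign under the 12 alternatives to floor, normalization, probe set, filter and local median. For single genes this was largely set beforehand. A floor cannot turn the sign of a ratio, and the rule for the largest ratios asked for probe sets of one sign. Of 1087 values of named genes under alternatives 962 moved by less than the SD between probe sets and 125 by more, and of 390 list medians 339 moved by less than the SD of random lists. The basal, mesenchymal, mitotic, interferon and cholesterol lists stayed outside that range in all 12, the mesenchymal median between 0.42 and 0.82. A ratio with a dim side is set by the floor, so signal near background limits the counts. Of the 22 lists inside that range 9 lay outside it in at least 1 alternative, 15 times in all. The causes of the other shifts were not tested. No paired analysis was possible because each population has 1 array.

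Without a floor 541 genes were at least 2-fold higher and 381 lower, all 308 and 218 genes of the main setting among them, and the medians were 0.82 (mesenchymal), 0.78 (fibroblast), 0.41 (leukocyte), 0.52 (interferon) and 0.28 (NF-kB). With the floor at the 25th percentile 1122 were higher and 835 lower, with medians of 0.013 (proteases), 0.58 (EGFR ligands), 0.21 (heat shock), 0.52 (interferon), 0.28 (NF-kB), -0.20 (Notch) and 0.11 (neural). With the floor at the 75th percentile 89 were higher and 66 lower, THY1 gave no value, and medians were 0.73 (mesenchymal), -0.13 (stem markers), 0.64 (proteases), 0.52 (interferon), -0.17 (NF-kB), -0.22 (cholesterol) and 0.11 (neural). The mean of probe sets gave 0.33 (simple epithelial), 0.25 (endothelial), -0.16 (replication) and -0.067 (Notch).

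Without the _x_at, _s_at and _a_at classes THY1 gave no value, and medians were 0.27 (stem markers), 0.050 (proteases), -0.21 (replication), 0.030 (hypoxia), -0.16 (NRF2), 0.011 (p53) and 0.52 (TGF-beta). The probe set with the smallest change gave 0.19 (simple epithelial), 0.42 (mesenchymal), 0.028 (proteases), -0.021 (heat shock), 0.32 (interferon), 0.078 (hypoxia), -0.16 (cholesterol) and 0.076 (TGF-beta). The filter on mean signal gave 0.41 (leukocyte), -0.048 (NF-kB) and 0.11 (neural). The offset gave 141 lower genes, 124 of them among the 218, a THY1 log2 ratio of 1.28, and medians of 0.76 (mesenchymal) and 0.24 (leukocyte). Subtraction of the local median gave 0.37 (basal), -0.20 (squamous), -0.058 (ETS), 0.18 (heat shock), 0.24 (NF-kB), -0.40 (cholesterol), 0.26 (TGF-beta) and -0.033 (ribosomal). At 1.5-fold 919 genes were higher and 843 lower, and at 4-fold 57 and 21. Under quantile normalization (317 higher, 211 lower), a median ratio of 0 (316, 208) and loess (322, 200) the counts stayed within 1.5 times.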

Other observations

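The tests on chance order, on a few strong genes, on copy number and on fibroblasts were chosen only after the result was seen, as was the subtraction of local medians as an alternative; the tests on scaling, gene span and second probe sets, and the bounds for the tests on local medians, were written before theirs. The genes of this paragraph were singled out after their values were seen. CASP1, the protease that activates IL18, was 3.83-fold higher in CD90+ cells, and CARD16, a CASP1 relative, 4.23-fold (390 against 92.2). The interferon-induced membrane proteins IFITM1, IFITM2 and IFITM3 were 2.33-fold, 2.52-fold and 2.82-fold higher; they are close copies. The kallikreins KLK6 and KLK8 were 2.57-fold and 2.78-fold higher. The chloride channel ANO1 was 6.10-fold higher (3585 against 588) while its neighbour CCND1 was 1.69-fold higher. The guidance receptor ROBO2 was 4.30-fold lower (95.0 against 409), the sodium channel SCN9A at least 4.41-fold and the adhesion molecule NRCAM 2.97-fold (655 against 1944).

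Runs of neighbouring genes shifted together, the lowest with a median log2 ratio of -0.62 over 50 genes, from PIAS2 to TIMM21 on chromosome 18. The tables argue against chance order (lowest of 1000 shuffles -0.27), against scaling that depends on signal (-0.61 after loess), against a trend with gene span (-0.59 after its removal) and against noise of single probe sets (median -0.64 over second probe sets of 29 of these genes). A few strong genes can hardly move a median over 50 genes, so the measure itself left little room for that explanation. The lowest run found from every other gene was another one, from RNF144A to ITSN2 on chromosome 2. There 91.7% of the 24 genes left out of the search were below 0, so the shift in that run was broad. A candidate explanation, as a hypothesis, is that the fractions differ in DNA copy number: with chromosome and split found from every other gene, the genes left out had a median of 0.03 over 38 genes and of -0.62 over 44 genes of chromosome 18, a step of -0.65, against at most 0.27 in size in 1000 shuffles put through the same search. Such a step is not specific to copy number, regional silencing stays open without DNA data, and GC content was not tested.

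Other runs also lay beyond every shuffle. Chromosome 2 held 3 lower runs, of 93, 187 and 294 genes, with medians of -0.41, -0.31 and -0.31. Higher runs lay on chromosome 12 from ERC1 to WBP11 (94 genes, 0.32), on chromosome 11 from FDX1 to TBCEL (63 genes, 0.33) and on chromosome 9 from KANK1 to LINGO2 (54 genes, 0.35). Inside the last one 6 genes were at least 2-fold lower and 4 at least 2-fold higher. Among the 6, the neighbours MTAP, KLHL9 and FOCAD were 2.44-fold, 2.31-fold and 2.67-fold lower, on 5, 3 and 2 concordant probe sets.

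Whether these runs account for genes at least 2-fold lower in CD90+ cells was tested by subtraction of each gene's local median, after which 167 of the 218 lower genes (76.6%) and 263 of the 308 higher genes (85.4%) remained beyond 2-fold. Bounds set beforehand were under 50% for the runs being the main source and 80% for their being none. The share of lower genes fell between them, so that test does not decide. Of the 177 lower genes among those ordered along the chromosomes, the lower runs held 43 (24.3%), against 9.29% of all ordered genes. The runs were found from the same genes, so this excess is no test. Most of these lower genes lay outside the lower runs, which argues against the runs as their main source. A smaller part stays open. All of the 24 genes named for the largest ratios remained beyond 2-fold, but this was set beforehand. The smallest of their ratios in size was -2.36 (SLPI), and the local median furthest from 0 among them was -0.30 (SLC8A1).

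For the higher mesenchymal genes, the median was 0.64 after loess and 0.64 after subtraction of local medians, each at percentile 100. Neither step lowered the median, but the percentiles do not test scaling or shifted runs. The random lists were already matched on signal. The highest median of neighbouring genes was 0.39, so its subtraction could hardly bring 0.64 into the central 95%. The protease median was 0.21 (percentile 98.4) after loess and 0.26 (percentile 99.9) after subtraction. That list fell inside the central 95% in 3 other alternatives. The tables argue against fibroblasts in the CD90+ sort. VIM gained 3817 signal units, while COL1A2, COL3A1, DCN and LUM, abundant in fibroblasts, read at most 47.5 in CD90+ cells. The median gain over the 16 genes of the fibroblast list was 0.27% of that of VIM. Of that list COL1A1 and PDPN, the latter also made by squamous carcinoma cells, gained over 10% of it. The test first chosen, the summed gain of COL1A1, COL1A2, COL3A1, DCN and LUM, gave 24.7% of the gain of VIM, between its bounds of 10% and 100%, with 885 of the 941 units from COL1A1; the other values were set against fibroblasts after that was seen. Signals of different probe sets are not on one scale, so shares of the gain of VIM are rough. The case against fibroblasts thus rests first on the source, since both fractions came from an established carcinoma line and not from tissue. Among the values it rests mainly on COL1A2, COL3A1, DCN and LUM, which stayed under the floor. A difference between CD90+ and CD90- cells themselves, in state or in clone, stays open and was not tested.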
